A study of Mus musculus with 8 samples.

How the data were processed

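Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in regulatory T (Treg) cells sorted from the spleens of mixed bone-marrow chimeric mice. Per the labels, the sorted cells carried the CD45.2 but not the CD45.1 form of the leukocyte marker, were CD4-positive and expressed a Foxp3-driven yellow fluorescent protein, so that cells of 1 donor in each chimera were taken. The donor was either wild type (WT) or carried a floxed Flcn gene with Foxp3-driven Cre recombinase (Flcn KO). Each group had 4 libraries, which the labels call biological replicates, and every sample was placed in its group by its title.

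The authors deposited 1 table of raw counts per peak and library over a shared set of 57199 peaks, with no normalization, in mm10 coordinates. Per the submitters' processing notes, Trimmomatic 0.36, BWA 0.7.16, Picard 2.9.4, SAMtools 1.9, MACS2 2.1.1 and bedtools 2.25.0 were used. The role and order of these tools, the treatment of duplicates, any shift of reads for the transposase, and whether peaks were called per library or on pooled libraries are not given in the sources used here. The peak starts in the deposited table count from 0 and were converted to count from 1. Of the peaks, 57104 lay on the main chromosomes and 95 on unplaced scaffolds; the median width was 351 bp, with a range of 2 to 2072 bp.

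The deposited counts summed to between 2723344 and 5111728 per library. Between 88.7% and 92.7% of a library's counts were even numbers, so both ends of most read pairs appear to be counted, and the number of independent fragments is closer to the count divided by 2. Without molecular identifiers, counts are also not independent molecules. The error of every value therefore rests on the spread between the replicate libraries and not on counting error alone. Pairs of libraries within a group differed by 2.17 to 3.73 in chi-square per peak, where sampling noise alone gives about 1 for independent counts and about 2 where both ends of each pair are counted. A library deposited again as a copy would give 0, and no pair did.

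Peaks were kept by edgeR's filterByExpr (minimum count of 10), which left 47859 of the 57199 peaks (83.7%). Library sizes were scaled by TMM, and Flcn KO was compared with WT by edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16, R 4.3.3), with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over all tested peaks, and a peak was called higher or lower at an adjusted p below 0.05. Log2 fold changes are Flcn KO minus WT, and their standard errors (SE) were derived from the fitted change and its F statistic. Normalised counts are edgeR's CPM values, counts relative to the TMM-scaled library size, given as mean ± SD over 4 libraries.

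Gene names came from a RefSeq gene table of assembly GRCm38.p6, the assembly behind mm10, holding 21883 protein-coding genes on the main chromosomes. That table gives the span of each gene but no strand, exons or introns, so transcription start sites could not be located as planned. After the files had been seen, the planned rule was replaced: a peak was assigned to the protein-coding gene with the nearest span within 50000 bp (a peak inside a gene has distance 0; ties went to the nearest gene end), and "promoter" was replaced by "within 1000 bp of either end of a protein-coding gene". Of all peaks, 63.9% lay inside a gene and 89.5% within 50000 bp of one. Assignment is by position alone and does not show which gene a peak regulates. Whether a peak inside a gene is exonic or intronic is not known here.

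Before the data were examined, 18 gene lists were fixed; 498 of the 509 list entries matched a distinct gene of the table. A list was tested as the set of tested peaks assigned to its genes, with limma's camera (limma 3.58.1) on voom values at a preset inter-peak correlation of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the 18 lists. The peaks named in the text also follow a rule fixed before the data were examined. They are up to 3 peaks each of Flcn, Foxp3, Tfeb, Tfe3 and Mitf; the 10 peaks with the largest positive and the 10 with the largest negative change among called peaks at or above the median level whose libraries did not overlap between groups; up to 4 called genes per list; and the 5 genes with the most called peaks in each direction. A largest-change peak beyond 50000 bp of a gene is named by its nearest gene with the distance. Further called peaks of a gene named by this rule are given beside it. A gene that the rule names is not reported here. A planned test of 27 sequence motifs and a planned GC-content correction need the genome sequence, which was not used here, and were not run.

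Alternatives were the size factors of DESeq2, library size alone, loess offsets, no low-count filter, a stricter filter, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom with sample weights, dispersion without robust fitting, other thresholds, a replicate block, and leaving out each library in turn. Halving the counts and thinning all libraries to the smallest total were added after the data had been seen. The peak test was tested on simulated data drawn for Flcn KO against WT over the 47859 peaks. In these data 200 peaks were changed, all at or above the median level, so recovery at lower levels was not tested. The test recovered 79% of the 2-fold and 100% of the 4-fold changes, and 13 of its 192 calls (6.8%) were false. In simulated lists of 100 peaks, limma's camera called a list moved by 0.3 log2 units and did not call an unmoved list. Simulated peaks were drawn independently of each other, so the list test was not tested where peaks are correlated.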

Results

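Regulatory T cells restrain immune responses and depend on the transcription factor Foxp3. Folliculin, the product of Flcn, acts at the lysosome in amino acid signalling to mTORC1 and keeps the transcription factors TFEB and TFE3 out of the nucleus. The comparison asks how loss of Flcn in Foxp3-expressing cells alters accessible chromatin, in cells that developed in mixed bone-marrow chimeras. Accessibility was measured as raw ATAC-seq counts over 57199 shared peaks in 4 WT and 4 Flcn KO libraries of sorted splenic Treg cells. The WT libraries held 4914976, 4499889, 3986331 and 4122933 counts for replicates 1 to 4, and the Flcn KO libraries 5111728, 3824571, 4101756 and 2723344. Mean depth did not differ detectably between the groups (exact two-sided permutation test, p = 0.486; the smallest p these 8 libraries allow is 0.029). Coordinates are in mm10.

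At the targeted gene itself, Flcn (chromosome 11, 59791408 to 59810039), neither tested peak passed the test. The peak at 59808986 to 59809376, inside the gene and 663 bp from its end, had 16.3 ± 3.76 CPM in WT and 13.6 ± 2.83 CPM in Flcn KO (SD, n = 4), a log2 fold change of −0.28 (SE 0.22, edgeR adjusted p = 0.679). The peak at 59809585 to 59809977 had 9.06 ± 3.00 and 6.09 ± 2.09 CPM, a log2 fold change of −0.57 (SE 0.31, adjusted p = 0.463). The labels do not say which exons the Cre deletes, so these peaks do not check the genotype. The genes of the folliculin-regulated transcription factors did not pass the test either: Tfe3 had a log2 fold change of −0.44 (SE 0.19, adjusted p = 0.296), the 3 Tfeb peaks lay between −0.43 and 0.03, and the 3 Mitf peaks between −0.19 and 0.84 (adjusted p = 0.215 for the last). The Foxp3 peaks, at 7583819 and 7586511 on chromosome X, had log2 fold changes of 0.12 (SE 0.16) and 0.30 (SE 0.25), with adjusted p = 0.831 and 0.692.

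Across the genome, accessibility rose at 644 peaks and fell at 489 peaks in Flcn KO, together 1133 of 47859 tested (2.37%, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 398 rose and 370 fell by at least 2-fold, and the median log2 fold change was 1.16 among the higher and −1.41 among the lower peaks. The groups' libraries did not overlap at 574 of the higher and 434 of the lower peaks; over all tested peaks this held for 7.6%, where chance gives 2.9%. An unadjusted p below 0.05 by edgeR was reached by 6156 of the 47859 tested peaks, the background for the list counts below. Of the 1133 called peaks, 913 had an assigned gene within 50000 bp. The higher ones were assigned to 438 genes and the lower ones to 350 genes, out of 13354 genes with an assigned tested peak. Without Flcn KO replicate 1 the calls came to 1797, of which 1000 were shared with the 1133, without WT replicate 2 they came to 665, with 217 lower peaks, and without Flcn KO replicate 3 the higher peaks fell to 420.

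Among the 359 higher peaks eligible by the naming rule, the 10 largest changes ran from 2.36 to 3.80 log2 units. Inside Fnip2, which encodes a folliculin-interacting protein, the peak at 79491579 to 79492091 of chromosome 3 rose from 3.76 ± 2.32 to 30.4 ± 4.81 CPM (SD, n = 4), 8.17-fold (log2 fold change 3.03, SE 0.28, edgeR adjusted p = 1.24e-08). A peak inside Col27a1, a fibrillar collagen gene, at 63222132 to 63222869 of chromosome 4 had the lowest adjusted p among all tested peaks (2.77e-12) and rose from 3.60 ± 1.39 to 40.1 ± 8.19 CPM (log2 fold change 3.47, SE 0.24). Peaks inside Fgf5, a fibroblast growth factor gene, and Frmpd1 rose by 3.50 (SE 0.40) and 3.03 (SE 0.30) log2 units. The others lay outside genes: 23.4 kb from Rpia, which encodes an enzyme of the pentose phosphate pathway (2.75), 18.6 kb from Rttn (2.38), 60.2 kb from Lrpap1 (2.40, adjusted p = 3.84e-11), 66.5 kb from Agbl1 (2.36), 152 kb from Hmga2 (2.44) and 1209 kb from Ndufa4 (3.80).

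Among the 204 eligible lower peaks, the 10 largest changes ran from −3.24 to −1.88. The largest lay 18.1 kb from Tmtc4, at 123001426 to 123001730 of chromosome 14, and fell from 27.1 ± 8.08 to 2.85 ± 0.958 CPM (log2 fold change −3.24, SE 0.28, edgeR adjusted p = 8.92e-10). A peak 1458 bp from the end of Tgfbr1, which encodes a TGF-beta receptor, at 47351458 to 47351764 of chromosome 4, fell from 20.1 ± 1.30 to 3.95 ± 0.453 CPM (−2.36, SE 0.25, adjusted p = 8.01e-08). Peaks near Rchy1, a ubiquitin ligase gene, and Tfap2a, a transcription factor gene, changed by −2.48 (SE 0.36) and −2.12 (SE 0.32). Peaks near Ythdc1, which encodes a reader of methylated RNA, near Sema6d (64.7 kb away) and near Npnt changed by −2.08, −2.08 and −2.03. Peaks near Lyn, a Src-family kinase gene, inside Lmnb1, which encodes lamin B, and inside Alpk2 changed by −1.96, −1.92 and −1.88. All 20 of these largest changes were called under every alternative in which they were fitted.

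**Figure D1:**
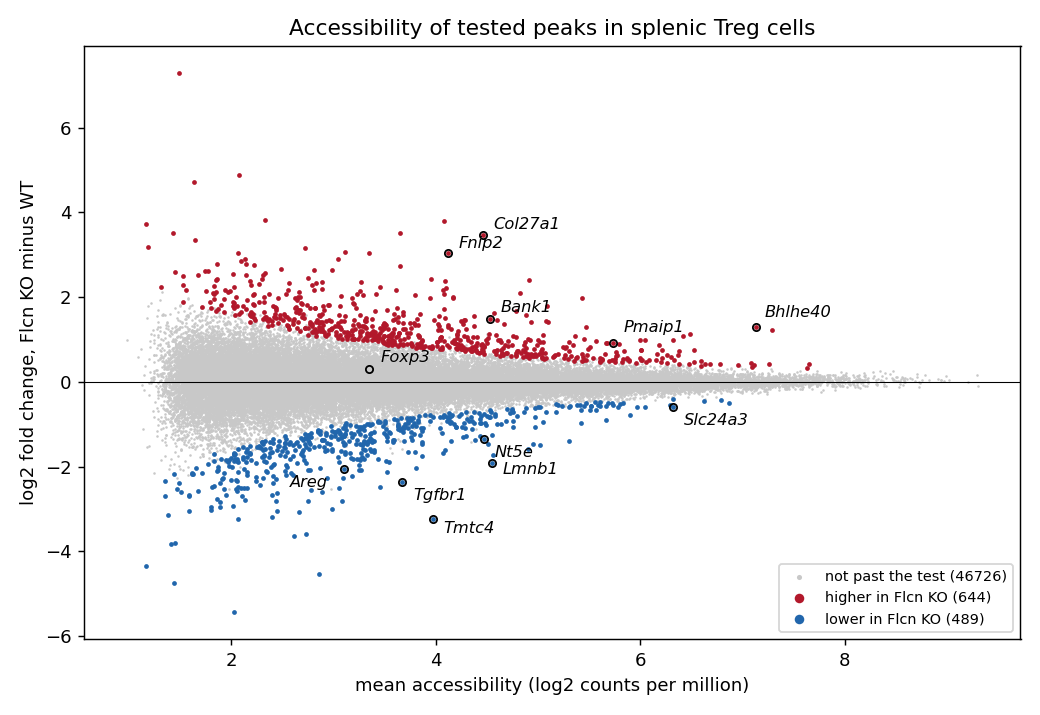
Log2 fold change (Flcn KO minus WT, vertical axis) against mean accessibility in log2 CPM (horizontal axis) for each of the 47859 tested peaks, with the 644 higher peaks in red, the 489 lower peaks in blue and the rest in grey. For 12 genes the peak with the lowest adjusted p among their named peaks is circled: Col27a1 and Fnip2 lie above 3, Tmtc4 lies at −3.24, and Foxp3 lies close to 0 with no call.

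Several genes carried more than 1 changed peak. Some of these peaks lie close together and may be parts of 1 accessible element, so the counts are of peaks and not of separate elements. The called Rpia peaks start at 70813962, 70814686 and 70815531, and called Bhlhe40 peaks at 108659187 and 108660123 are also close. So are called Galnt9 peaks at 110594505 and 110595365. Bhlhe40, which encodes a basic helix-loop-helix transcription factor active in T cells, had 3 of 10 tested peaks higher, by 0.99 to 1.28 log2 units. The strongest, at 108660123 to 108660826 of chromosome 6 and overlapping an end of the gene, rose from 81.5 ± 8.13 to 199 ± 20.2 CPM (SD, n = 4), 2.44-fold (SE of the log2 fold change 0.10, edgeR adjusted p = 3.84e-11). Bank1, which encodes a B cell scaffold protein, had 4 of 7 peaks higher (0.73 to 1.60), and Gfra2, which encodes a receptor for a neurotrophic factor, had 4 of 5 (1.15 to 1.43). Pkp4 had 3 of 11 (1.05 to 1.42) and Rpia 3 of 12 (1.59 to 2.75). Nfia, a transcription factor gene, had 4 of 31 peaks lower (−3.60 to −1.46). Arhgap10 had 4 of 21 lower (−2.83 to −1.36) and 1 higher. Galnt9, Slc24a3, which encodes an ion exchanger, and Alcam, which encodes an adhesion molecule, each had 3 lower peaks, of 4, 7 and 9 tested, with ranges of −1.87 to −0.98, −1.74 to −0.60 and −1.63 to −0.55. The Alcam peak with the lowest adjusted p was not called without WT replicate 2 or by limma-voom (adjusted p up to 0.14).

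Among genes of Treg identity, 5 of 219 peaks rose, 2 fell and 212 did not pass; adjusted over the list alone, 6 rose and 2 fell. Nt5e, which encodes the ectonucleotidase CD73, held a peak that fell from 30.7 ± 7.76 to 12.2 ± 2.41 CPM (SD, n = 4; log2 fold change −1.34, SE 0.20, edgeR adjusted p = 5.93e-05) and another that rose by 0.998 log2 units (SE 0.25). A peak 6.1 kb from Ctla4, which encodes an inhibitory receptor, fell from 11.3 ± 1.96 to 4.63 ± 1.64 CPM (−1.24, SE 0.29, adjusted p = 0.0127). Peaks at or near Dusp4, a phosphatase gene (1.05), and Ikzf2, which encodes Helios (1.11 and 0.63), rose. The Ctla4 call ended without WT replicate 2 or Flcn KO replicate 4 (adjusted p up to 0.071), the Dusp4 call without Flcn KO replicate 3 (0.058), and that of the first Ikzf2 peak without WT replicate 2 or 3 or Flcn KO replicate 3 or 4 (up to 0.12).

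Among effector and tissue Treg genes, 3 of 256 peaks rose, 6 fell and 247 did not pass; adjusted over the list alone, 4 rose and 7 fell. Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, had 2 lower peaks: 1 lies 15.1 kb away and fell from 12.8 ± 5.28 to 2.92 ± 1.12 CPM (SD, n = 4; log2 fold change −2.07, SE 0.34, edgeR adjusted p = 0.000183), and the other overlaps an end of the gene and changed by −1.18 (SE 0.27). A peak inside Tigit, an inhibitory receptor gene, fell from 9.78 ± 3.29 to 2.36 ± 1.06 CPM (−2.09, SE 0.37, adjusted p = 0.000489). A peak 16.1 kb from Il10, which encodes the immunosuppressive cytokine interleukin-10, fell from 8.35 ± 2.96 to 2.29 ± 1.28 CPM (−1.83, SE 0.39, adjusted p = 0.00459). In the other direction, a peak 4.8 kb from Il1rl1, which encodes the interleukin-33 receptor ST2, rose from 6.57 ± 1.45 to 15.6 ± 3.71 CPM (1.26, SE 0.26, adjusted p = 0.00276). The list's median was 0.01 and its mean −0.04, and its set test pointed down (camera adjusted p = 0.88).

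Among naive and resting T cell genes, 3 of 386 peaks rose, 1 fell and 382 did not pass; adjusted over the list alone, 1 rose and 0 fell. A peak inside Pik3ip1, which encodes an inhibitor of phosphoinositide 3-kinase, rose from 6.05 ± 0.827 to 15.7 ± 2.16 CPM (SD, n = 4; log2 fold change 1.38, SE 0.25, edgeR adjusted p = 0.000663). Inside Foxp1, a forkhead transcription factor gene, 1 peak changed by −0.83 (SE 0.22) and another by 0.67 (SE 0.18), and a peak near Dapl1 rose by 0.62 (SE 0.17). The first Foxp1 call ended by limma-voom and without WT replicate 1 or 2 or Flcn KO replicate 2, 3 or 4 (adjusted p up to 0.19), and the Dapl1 call without WT replicate 2, 3 or 4 or Flcn KO replicate 2, 3 or 4 (up to 0.21). At an unadjusted p below 0.05, 40 peaks of this list were higher and 15 lower, beside 6156 of 47859 in either direction over all tested peaks.

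Among lysosome and autophagy genes of the CLEAR network, which TFEB and TFE3 are known to regulate, 4 of 147 peaks rose, 0 fell and 143 did not pass, with the same counts adjusted over the list alone. At an unadjusted p below 0.05, 15 were higher and 4 lower, beside 6156 of 47859 in either direction over all tested peaks. DESeq2 and limma-voom called 4 and 3 higher and 0 lower. The 4 peaks lay inside Fnip2 and Ppargc1a, which encodes a coactivator of mitochondrial biogenesis. Beside the Fnip2 peak above, a Fnip2 peak at 79468165 to 79468534 held 2, 0, 0 and 1 counts in WT replicates 1 to 4 and 30, 20, 14 and 18 in Flcn KO (edgeR adjusted p = 3.34e-05). At Ppargc1a, a peak overlapping an end of the gene (52115662 to 52116278 of chromosome 5) rose from 13.7 ± 2.23 to 23.9 ± 3.53 CPM (SD, n = 4; log2 fold change 0.82, SE 0.20, adjusted p = 0.0134), and another rose by 1.33 (SE 0.36). The first Ppargc1a call ended without WT replicate 2 (adjusted p = 0.080, the highest over the alternatives, the lowest being 0.0072). The list's median change was 0.00 and its mean 0.13, and 74 of the 147 peaks lay above 0.

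Among mitochondrial dynamics and mitophagy genes, 1 of 63 peaks rose, 3 fell and 59 did not pass; adjusted over the list alone, 1 rose and 4 fell. A peak inside Yme1l1, which encodes a protease of the inner mitochondrial membrane, rose by 1.60 log2 units (SE 0.26, edgeR adjusted p = 0.000183), while peaks at or near Mcu, the mitochondrial calcium uniporter gene, changed by −1.58 (SE 0.34) and −0.86 (SE 0.23), and a peak inside Chchd3, which encodes a cristae-organising protein, by −1.78 (SE 0.43). Among electron transport chain and ATP synthase genes, 1 of 75 peaks rose, at Sdhb, a succinate dehydrogenase subunit gene (1.64, SE 0.41), 0 fell and 74 did not pass, with 1 and 0 adjusted over the list alone; at an unadjusted p below 0.05, 2 were higher and 2 lower. Among mTORC1, amino acid sensing and AMPK genes, 1 of 95 peaks rose, near the arginine sensor gene Castor1 (1.01, SE 0.26), 1 fell, near Sesn3 (−0.60, SE 0.17), and 93 did not pass, with 1 and 1 adjusted over the list alone. Among integrated stress response genes, 1 of 49 peaks rose, inside Eif2ak3, which encodes the kinase PERK (1.31, SE 0.32), 0 fell and 48 did not pass, with 1 and 0 adjusted over the list alone. At an unadjusted p below 0.05, 5 stress response peaks were higher and 2 lower. Among glycolysis genes, 0 of 87 peaks rose, 1 fell, near Myc (−0.79, SE 0.22), and 86 did not pass, with 0 and 0 adjusted over the list alone. Among cholesterol and fatty acid synthesis genes, 0 of 57 rose, 1 fell, inside the lanosterol synthase gene Lss (−1.86, SE 0.45), and 56 did not pass, with 0 and 1 adjusted over the list alone. At an unadjusted p below 0.05 these last lists had 1 and 3 peaks higher and 3 and 2 lower; DESeq2 called the same numbers as edgeR and limma-voom called 0 in both. DESeq2 and limma-voom called 1 higher and 0 lower peaks in the electron transport and stress response lists.

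Some of these peaks held few counts in 1 group. Replicates 1 to 4 held 10, 7, 8 and 10 counts in WT at Sdhb and 14, 18, 12 and 20 in WT at Eif2ak3. In Flcn KO they held 8, 4, 4 and 6 at Lss and 14, 2, 6 and 8 at Chchd3. Several of the calls in these lists ended when 1 of several libraries was left out, with the direction kept. The log2 fold change ranged over all alternatives from 1.48 to 1.87 for Sdhb, −2.07 to −1.47 for Chchd3, 1.20 to 1.47 for Eif2ak3, −2.08 to −1.72 for Lss, 0.92 to 1.09 for Castor1, −0.75 to −0.46 for Sesn3 and −0.88 to −0.66 for Myc. The Sdhb and Chchd3 calls each ended without WT replicate 2 or Flcn KO replicate 2 or 3 (edgeR adjusted p up to 0.099 and 0.089), the Eif2ak3 call without WT replicate 1 or Flcn KO replicate 2 (up to 0.074), and the Lss call by limma-voom and without WT replicate 1 or Flcn KO replicate 2 or 3 (up to 0.088). The Castor1 call ended without WT replicate 1, 2 or 4 or Flcn KO replicate 2 or 4 (up to 0.094), the Sesn3 call with the stricter filter, by limma-voom, with thinned counts and without any single library other than WT replicate 1 or Flcn KO replicate 3 (up to 0.17). The Myc call ended by limma-voom, with thinned counts and without any single library other than WT replicate 4 (up to 0.24).

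**Figure D2:**
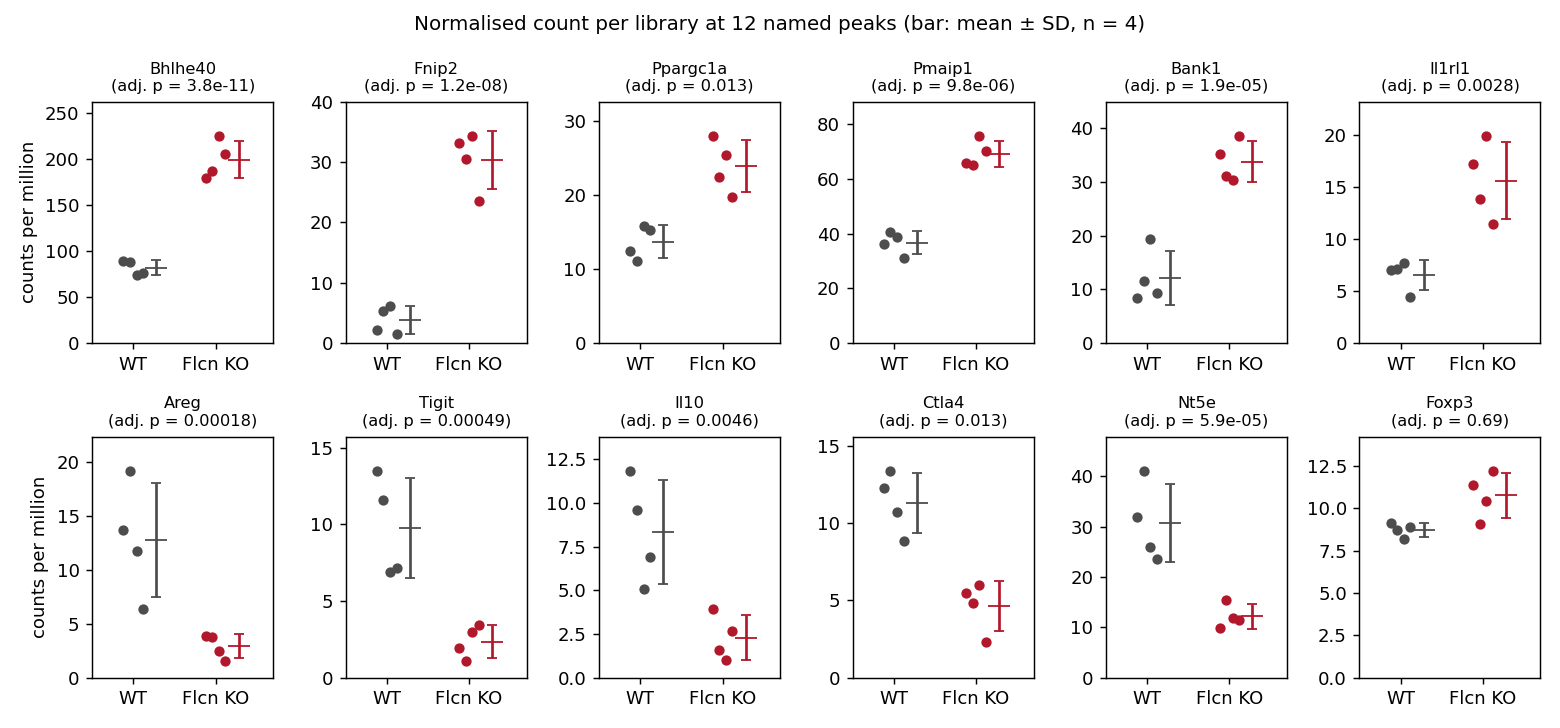
Normalised count (CPM, vertical axis from 0) in each WT (grey) and Flcn KO (red) library at 12 peaks, 1 point per library, with the mean ± SD of 4 libraries beside the points and the edgeR adjusted p above. Bhlhe40, Fnip2, Ppargc1a, Pmaip1, Bank1 and Il1rl1 were higher and Areg, Tigit, Il10, Ctla4 and Nt5e lower in Flcn KO, while the Foxp3 peak was not called.

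Among T helper cytokine and lineage genes, 2 of 111 peaks rose, 3 fell and 106 did not pass; adjusted over the list alone, 4 rose and 4 fell. A peak inside Il12rb2, an interleukin-12 receptor gene, rose from 3.87 ± 0.750 to 10.3 ± 1.03 CPM (SD, n = 4; log2 fold change 1.41, SE 0.30, edgeR adjusted p = 0.00442), and a peak 15.4 kb from Ifng, which encodes interferon-gamma, rose by 0.60 (SE 0.17). Peaks inside Stat4, which encodes a signal transducer of interleukin-12, changed by −1.75 (SE 0.43) and −1.03 (SE 0.29). Among interferon response genes, 0 of 67 peaks rose, 2 fell and 65 did not pass; adjusted over the list alone, 1 rose and 2 fell. A peak near Gbp4, a guanylate-binding protein gene, changed by −0.84 (SE 0.21). At an unadjusted p below 0.05, 4 interferon response peaks were higher and 6 lower; DESeq2 called 1 higher and limma-voom 0.

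Among apoptosis genes, 2 of 110 peaks rose, 0 fell and 108 did not pass, with the same counts adjusted over the list alone; at an unadjusted p below 0.05, 5 were higher and 2 lower. A peak 5.1 kb from Pmaip1, which encodes the pro-apoptotic protein NOXA, rose from 36.6 ± 4.17 to 69.1 ± 4.83 CPM (SD, n = 4; log2 fold change 0.92, SE 0.12, edgeR adjusted p = 9.84e-06), and a peak inside the death receptor gene Tnfrsf10b rose by 0.41 (SE 0.10). DESeq2 and limma-voom also called 2 higher and 0 lower apoptosis peaks. Among cell cycle genes, 0 of 121 peaks were called by edgeR, DESeq2 or limma-voom, and 7 were higher and 5 lower at an unadjusted p below 0.05. The Ifng call ended without WT replicate 2, 3 or 4 or Flcn KO replicate 2, 3 or 4 (adjusted p up to 0.19) and the Tnfrsf10b call without WT replicate 1, 2 or 4 or Flcn KO replicate 2, 3 or 4 (up to 0.085). The stronger Stat4 call ended without WT replicate 2 or 4 or Flcn KO replicate 3 or 4 (up to 0.079) and the Gbp4 call without WT replicate 1, 3 or 4 or Flcn KO replicate 1 or 2 (up to 0.071).

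Genes that mark other cell types also held changed peaks. Among B cell marker genes, 4 of 26 peaks rose, all at Bank1, 1 fell, near Cd22 (log2 fold change −1.25, SE 0.33), and 21 did not pass; adjusted over the list alone, 6 rose and 1 fell. The Bank1 peak with the lowest adjusted p, at 136072005 to 136072486 of chromosome 3, rose from 12.2 ± 5.01 to 33.8 ± 3.82 CPM (SD, n = 4; 1.48, SE 0.21, edgeR adjusted p = 1.92e-05). This was the only list of the 18 that passed the set test at the preset correlation (camera adjusted p = 0.020). It did not pass with an estimated correlation (adjusted p = 0.32 with an estimated correlation), where 0 of 18 lists passed and 2 had an unadjusted p below 0.05. Without Bank1, a set chosen after the result was seen, the 19 remaining peaks had a median log2 fold change of 0.11 and the list no longer passed the set test (camera adjusted p = 0.73). The Cd22 call ended by limma-voom, with thinned counts, and without WT replicate 1 or 3 or Flcn KO replicate 2, 3 or 4 (adjusted p up to 0.13).

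Among CD8 T and NK cell marker genes, 3 of 39 peaks rose, 1 fell and 35 did not pass; adjusted over the list alone, 6 rose and 1 fell. Peaks near Klrk1, which encodes the activating receptor NKG2D, rose by 1.38 (SE 0.22, edgeR adjusted p = 1e-04) and 1.44 (SE 0.36). At Klrb1c, which encodes the NK cell receptor recognised as NK1.1, a peak inside the gene changed by −1.57 (SE 0.38) and a peak 17.3 kb away rose by 0.50 (SE 0.13). The inner Klrb1c call ended by limma-voom, with thinned counts, and without WT replicate 2 or Flcn KO replicate 2 or 4 (adjusted p up to 0.12). Among erythroid marker genes, 1 of 15 peaks rose, near the transcription factor gene Gata1 (1.04, SE 0.22, adjusted p = 0.00354), 0 fell and 14 did not pass. Adjusted over the list alone, 3 rose and 0 fell. At an unadjusted p below 0.05, 3 were higher and 0 lower, and DESeq2 and limma-voom each called 1 higher and 0 lower. Among myeloid cell marker genes, 0 of 29 peaks were called by edgeR, DESeq2 or limma-voom, and 2 were higher and 2 lower at an unadjusted p below 0.05.

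By fry, which asks whether a list's peaks move on balance in 1 direction without comparing them with other peaks, the CLEAR network (adjusted p = 0.026) and the erythroid marker genes (adjusted p = 0.0049) passed, both with the direction up. Neither passed camera, with adjusted p = 0.41 and 0.091 at the preset correlation and adjusted p = 0.42 and 0.32 with an estimated correlation. The fry call of the CLEAR network ended without WT replicate 1, 3 or 4 or Flcn KO replicate 1. It also ended with the replicate block, with the stricter filter and for gene-end peaks alone (fry adjusted p from 0.073 to 0.60 over these settings). The fry call of the erythroid marker genes ended without WT replicate 3, with the replicate block, with the stricter filter and for gene-end peaks alone (0.052 to 0.60). The median of the 15 erythroid peaks, on limma-voom values, was 0.34, but −0.01 without WT replicate 3, 0.14 with no low-count filter and −0.22 for gene-end peaks alone. By its mixed form, which asks for change in either direction, 13 of the 18 lists passed. Median, mean and the direction of the set test differed in sign for integrated stress response genes (median −0.07, mean 0.02, test down). For electron transport genes they were 0.00, −0.02 and up. Together the lists covered 1933 tested peaks, of which 52 were called, beside 1133 of 47859 (2.37%) over all tested peaks.

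**Figure D3:**
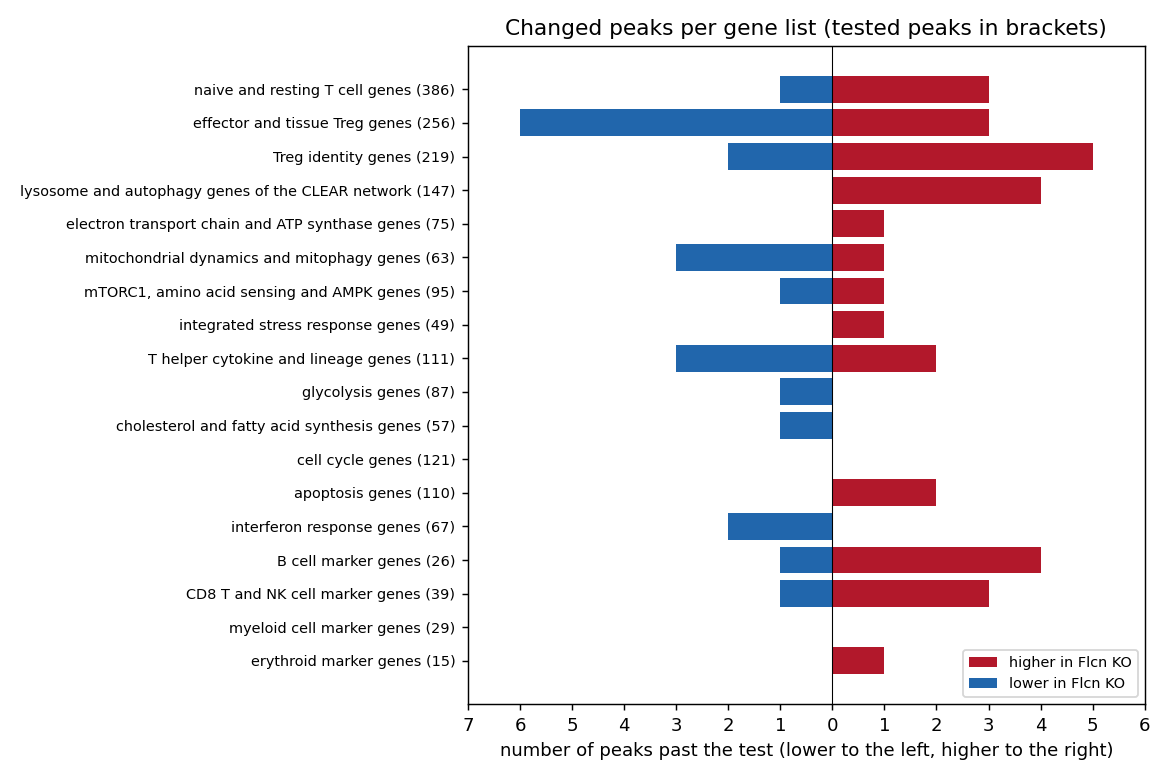
Number of peaks past the edgeR test in each of the 18 gene lists (bars from 0, higher in Flcn KO to the right in red, lower to the left in blue), with the number of tested peaks in brackets. Effector and tissue Treg genes had 3 higher and 6 lower peaks, Treg identity genes 5 and 2, and the CLEAR network 4 and 0.

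The changed peaks lay away from gene ends. Of the called peaks on chromosomes with annotated genes, 75 of 1131 (6.6%) lay within 1000 bp of either end of a protein-coding gene, against 11741 of 46648 (25.2%) of the peaks that were not called (odds ratio 0.211, 95% interval 0.165 to 0.267, Fisher's exact test, two-sided p = 1.05e-58). The share was 5.8% among the higher and 7.8% among the lower peaks. The gene-end peaks of Bhlhe40, Ppargc1a, Areg and Slc24a3 were among the exceptions. The share was below that of uncalled peaks at each level of accessibility, with 5.4% against 10.5% at the lowest of 4 equal levels of mean accessibility and 11.7% against 51.0% at the highest. Peaks are not independent replicates, so this p describes where the called peaks lie.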

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

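The check for a library far from its group was fixed before the data were seen, while the look at Flcn peaks left out of the test was chosen after the result was seen. Within the groups of 4 libraries, at each named peak (log2 level) and for the library totals, a library was picked out where its gap to the nearest other library, divided by the group's range, exceeded Dixon's 95% critical value for 4 samples. This held in 5 of 148 groups, where chance gives about 7.4. At the Flcn peak starting at 59809585, Flcn KO replicate 3 had 2.98 CPM against 6.86 to 7.48 in the other Flcn KO libraries. At the Tfeb peak starting at 47739513, Flcn KO replicate 2 had 9.35 CPM against 7.43 to 7.62. At the Mitf peak starting at 97978135, Flcn KO replicate 1 had 6.65 CPM against 9.62 to 10.3. At the Agbl1 peak starting at 76162702, Flcn KO replicate 3 had 24.4 CPM against 12.3 to 13. At the Il1rl1 peak starting at 40399558, WT replicate 4 had 4.43 CPM against 7.06 to 7.65 in the other WT libraries.

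Inside Flcn, 2 further peaks fell below the low-count filter and held counts almost only in Flcn KO. The peak at 59798675 to 59798950 held 0, 2, 0 and 0 counts in WT replicates 1 to 4 and 16, 4, 8 and 16 in Flcn KO replicates 1 to 4, in sum 2 against 44. The peak at 59799302 to 59799641 held 0, 0, 2 and 0 counts in WT and 2, 9, 18 and 21 in Flcn KO, in sum 2 against 50. With no filter, edgeR gave adjusted p = 0.0086 and 0.0055. Among the 9340 untested peaks, 17 had every Flcn KO library above every WT library with at most 3 counts summed over WT. By raw counts, every Flcn KO library lay above every WT library at 154 untested peaks. The reverse held at 326, where chance gives about 133 for each. No explanation for the Flcn counts was tested.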

How the results depend on the processing

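Halved counts and thinned libraries were chosen as alternatives after the data had been seen; the others were planned. No called peak changed direction under any alternative. Higher peaks, 644 in the report, came to 571 to 736 and lower peaks, 489 in the report, to 388 to 639 under other scalings, tests and dispersions, no filter, the replicate block, halved counts and thinning. The stricter filter gave 428 higher and 217 lower peaks from fewer tested peaks. A log2 fold change of at least 1 left 398 higher and 370 lower, and an unadjusted p below 0.05 with a log2 fold change of at least 0.5 gave 2620 and 2180. Leaving out 1 library gave 420 (without Flcn KO replicate 3) to 863 (without Flcn KO replicate 1) higher and 217 (without WT replicate 2) to 934 (without Flcn KO replicate 1) lower peaks. The gene-end share ranged from 5.7% to 8.3% across these, and was 7.1% with loess offsets and 11.1% within 2500 bp. The number of lists called, 1 in the report, was 0 with an estimated correlation, with no filter and for gene-end peaks alone, 2 with the replicate block, and 0 to 3 leaving out 1 library; the cause was not tested. The labels state no pairing of libraries by replicate number, and whether the numbers pair them is not settled here. Same-number correlations were 0.08, −0.05, 0.06 and 0.05, and 1 of 4 WT libraries was closest to its own number. The strongest correlations across the groups were with Flcn KO replicate 1, at 0.175 for WT replicate 2 and −0.152 for WT replicate 3. The replicate block gave 736 higher and 639 lower peaks. Of 62 named called peaks, 41 stayed called under every other scaling, filter, test, dispersion, block, unit, depth and left-out library that kept them, thresholds aside, and 21 lost the call somewhere. The GC-content corrections and the motif test were not run. Flcn KO replicate 4, the shallowest library, held 2723344 counts. The low-count filter left out 9340 peaks, of which 149 were called with no filter.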

Other observations

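The splits of the libraries and the flank test on chromosome 12 were fixed before their results were seen; the other tests below were chosen only after the result was seen. The regions of the antigen receptor genes were chosen after seeing the data. The bootstrap intervals of the medians below were drawn by resampling peaks and not libraries. They treat peaks as independent and do not measure the spread between libraries. Across the T cell receptor alpha and delta region (chromosome 14), 1 of 81 tested peaks was higher and 0 lower, with a median log2 fold change of 0.02 (bootstrap 95% interval −0.06 to 0.22), and across the T cell receptor beta region (chromosome 6) 1 of 39 was higher and 0 lower, with a median of 0.11 (−0.01 to 0.18). Across the V segments of the immunoglobulin heavy-chain region (chromosome 12, 113.57 to 116.01 Mb), 0 of 84 peaks were higher and 11 lower (edgeR; 0 and 31 at an unadjusted p below 0.05, 0 and 10 by DESeq2, 0 and 9 by limma-voom), 74 lay below 0, and the median was −0.44 (−0.56 to −0.33). Their summed level was 993 ± 71.5 CPM in WT and 743.8 ± 88.5 CPM in Flcn KO (SD, n = 4, exact permutation test, p = 0.029, the smallest possible). Leaving out each library gave medians of −0.55 to −0.39.

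For the lower heavy-chain V peaks, fewer B cells among the sorted Flcn KO cells, which a gate on CD4 and Foxp3 should already remove, predict a fall at B cell genes, but the B cell marker peaks had a median log2 fold change of 0.21 (0.08 to 0.50), and 0.11 in the 19 peaks without Bank1. Single B cell genes were mixed: a Cd22 peak was called at −1.25, the uncalled Ebf1 and Pax5 peaks, chosen after their values were seen, lay from −0.64 to 0.17 and −0.40 to 0.11, and the 6 kappa-region peaks (−0.07, −1.14 to 0.38) were too few to tell. A loss of DNA copies predicts 1 common fold. Cochran's Q was 2.52 times its degrees of freedom (a common fold alone gives about 1), with called peaks from −2.30 to −0.48. This weighs against a loss of the whole region as the only change, in all or part of the cells. A loss of the whole region with other changes on top was not tested, and a loss of part of the region stays open. The 153 peaks within 2 Mb on either side had a median of −0.02 (−0.09 to 0.04) and 0 calls by edgeR, DESeq2 or limma-voom, with 2 higher and 8 lower at an unadjusted p below 0.05. Donor haplotype and read mapping among similar V segments were not tested, and genotype remains the biological alternative.

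Neighbouring called peaks tended to share a direction. Of 251 neighbouring pairs within 100 kb, 200 (79.7%) had the same direction, against a mean of 50.9% and a maximum of 62.9% over 10000 shuffles of the directions (permutation p = 1e-04, the smallest possible). Among the 201 pairs 5 to 100 kb apart, which removes most cases of 1 element called as several adjacent peaks, 151 (75.1%) did, against a maximum of 62.7%. Chance placement and split elements thus do not account for the whole excess, and no biological explanation was tested.

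A run of higher peaks lay in and beside Gfra2 on chromosome 14 (called peaks at 70.96 to 71.30 Mb). Of the 12 tested peaks with Gfra2 as nearest gene, which include an uncalled peak at 70894126 outside this range, 10 were higher, 0 lower (edgeR) and all 12 lay above 0, with called changes from 1.15 (SE 0.27) to 3.07 (SE 0.34) log2 units. A gain of DNA copies of the whole block predicts 1 common fold. A ceiling of 1 log2 unit was also set for it after the result was seen, but a larger gain could exceed this. The highest peak lay 6.2 standard errors above 1 log2 unit, and a second peak had 2.21 (SE 0.24). These heights alone therefore cannot decide against a larger gain. The highest and lowest called changes, picked as the extremes of 10, differed by 4.5 standard errors. A gain with other changes on top was not tested.

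Of the 35 splits of the 8 libraries into 4 and 4, 1, the split by genotype, called as many as 1133 peaks. The highest other called 166. A share of 1 in 35 is the smallest these splits allow. Every other split mixes the genotypes, so a real difference between them adds spread within its groups and lowers its count. The size of the gap therefore does not measure chance. For the number of gene lists called, 14 of the 35 splits reached the real value of 1, and the highest other called 4, so chance cannot be excluded. On the first principal component (28.5% of the variance), Flcn KO replicate 1 lay at 0.4, between the WT libraries (−61.6 to −26.3) and the other Flcn KO libraries (38.3 to 90). WT replicates 1 and 2 lay at −53.5 and −61.6, and WT replicates 3 and 4, nearer to Flcn KO, at −26.3 and −38.2.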
